A study of Mus musculus with 3 samples.

How the data were processed

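The samples were 3 mouse libraries of the D3 ES cell line, 1 each from ES cells at day 0, control EBs at day 4 and Brachyury knockdown EBs at day 4. Groups were taken from the sample titles. RNA was extracted with TRIzol LS and libraries were made with the Illumina mRNA-seq kit, per the labels' protocols. Bowtie and Cuffdiff and the mouse build mm9 are named in the submitters' processing notes, without versions. The gene annotation, the read length and the number of reads are not given in the sources used here.

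The data used were 2 deposited tables of 36808 genes with the FPKM of 2 libraries each, per the file headers. FPKM are fragment counts that the authors scaled by transcript length and library size, and no longer counts. The deposited tables also hold the natural log of the fold change, which matched the log of the FPKM ratio to within 5e-05, and an unadjusted p-value by the authors. A column of q-values or of test status was not used here, so the authors' call was taken as an unadjusted p under 0.05 and not, as planned, as a significance column. The column named for EBs at day 4 in the first table was taken as the control library, whose column in the second table is named nontarget. The title and column name of the ES cells do not say whether they had a nontarget treatment too. The control values in the 2 tables were exactly equal for 65.2% of all 36808 genes, a share that counts genes at 0 in both. They were within 1% for 79.1% of the 18037 genes above 0 in either.

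An FPKM of 0 can be a failed estimate. Of the control values, 133 were 0 in the first table and at least 5 FPKM in the second, and 54 the reverse. Ctnnb1 was listed at 0 in both libraries of the first table and at 320 and 417 FPKM in the second. Genes at 0 are therefore given as listed at 0, without a fold. The control values differed over 1.5-fold, on FPKM + 1, for 314 genes. Comparisons were made within a table, and where values of all 3 libraries stand side by side they come from both.

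Symbols that had been turned into dates in 25 rows were looked up by gene ID. Of the gene IDs, 31838 were found in GENCODE M21, a later annotation on another build, which was used for names, biotypes and lengths and not for coordinates. Coordinates are those of the deposited loci on mm9, with 1 added to the start. Such a locus can span several genes, and 13646 genes shared theirs with another gene. Whether counting used strand is not known here, so overlapping genes are uncertain, as are genes with near-identical copies.

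Short RNAs and rows without a name were left out and rows of the same symbol were summed. Genes with at least 1 FPKM in either library were compared by the difference of log2(FPKM + 1). A difference of at least 1 is called higher or lower. It understates the change of low genes, and folds given in the text are ratios of the FPKM themselves. With 1 library per group there was no test. The authors' p gives an error per library, as a standard deviation on the natural log scale, of 0.885 for genes near 1 FPKM and 0.107 for genes near 100 FPKM, which leaves single low genes imprecise. That error covers 1 library against another and not the spread between cultures.

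The 34 gene lists, the size rule and the rule for named genes were fixed before the data were examined. Of 522 list entries, 515 were matched by gene ID and 4 by symbol. For each list with 3 or more measured members the median difference was set against 10000 random lists of the same size, matched on mean log2(FPKM + 1) in 20 bins. Its percentile describes these libraries. Named genes were T, the 8 highest and 8 lowest genes with at least 5 FPKM in either library and a proper symbol, and up to 4 members of each list with the greatest difference. Some of these are covered by the counts of their lists alone. The result of 1 list is not reported here.

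The overlap of the comparisons was set beside the overlap of independent lists and beside 100 simulations of unchanged libraries that share the control. The simulation with scaled error and that with a floor of 20 FPKM were added after seeing the data. A first test for slower differentiation took genes higher in control EBs than ES cells that also differed in the knockdown, of which 32.4% were higher still. It chose genes on the shared control and was replaced after its result was seen, and the genes and bounds of the new test were set after a trial of it had been seen. The calling steps were tested on simulated data with 200 planted genes, which returned 100% of the 3-fold and 4-fold changes and 0 unchanged genes in each comparison. The planted genes had at least 5 FPKM, and the simulated noise was smaller than the median of the authors' error at every expression level. The result checks the calling steps and gives no rate of false calls at that error. Alternatives were pseudocounts of 0.1 and 0.5, no floor or a floor of 5 FPKM, 2 other scalings, a 3-fold rule, short RNAs kept, the highest of rows with the same symbol, and the authors' p as a further condition. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.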

Results

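Messenger RNA was sequenced from mouse embryonic stem (ES) cells of the D3 line at day 0, from embryoid bodies (EBs, aggregates in which ES cells differentiate) at day 4, and from day 4 EBs with a knockdown of Brachyury, the T-box transcription factor encoded by T. Each of the 3 groups was 1 library of whole cultures, so no difference has a replicate check and no test was run. Genes are called higher or lower by a rule of size alone, a difference of at least 1 in log2(FPKM + 1), which is 2-fold on that scale. The values were deposited as FPKM in 2 tables, one for ES cells and control EBs and one for control EBs and knockdown EBs. The control library, named nontarget in the second table, was therefore quantified in both tables and is shared by both comparisons. Read counts were not used here and the depth of each library is unknown. FPKM summed to 568352 in ES cells, to 781453 and 786277 in the first and the second quantification of control EBs, and to 760578 in knockdown EBs. At least 1 FPKM was reached by 12950 genes in ES cells, 12928 and 13044 in control EBs, and 13541 in knockdown EBs.

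The targeted gene was measured first in every library. T (ENSMUSG00000062327, chromosome 17, 8627288 to 8635361 on mm9) was at 0.297 FPKM in ES cells, at 254 FPKM in control EBs and at 2.47 FPKM in knockdown EBs. It was 857-fold higher in control EBs than in ES cells, with p = 0.000236 in the authors' deposited table. The size of this fold is imprecise, since the median error near the ES cell value was 1.95 on the natural log scale. T was 103-fold lower in knockdown than in control EBs, with p = 4.77e-13 in the authors' deposited table. The knockdown value was 0.970% of the control value, in the direction its label gives.

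The first comparison asked which genes differed between undifferentiated ES cells and control EBs after 4 days. Naive pluripotency genes were lower and primitive streak, node and primed epiblast genes were higher in control EBs. All 15 measured naive pluripotency genes were lower, with a median log2 difference of −4.54, at percentile 0 of 10000 random lists matched on expression. Zfp42 was at 467 FPKM in ES cells and 5.51 in control EBs, and the orphan nuclear receptor gene Esrrb at 169 and 1.30. Klf4 was at 118 and 1.18 FPKM, and Gbx2 at 70.9 and 0.218. Of 11 general pluripotency genes 9 were lower and 1 was higher (median −1.44, percentile 0.01), among them Fgf4 (63.6 and 0.847 FPKM) and Utf1 (304 and 29.4 FPKM).

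Of 18 primitive streak genes 15 were higher in control EBs and 0 were lower (median 3.66, percentile 100). Besides T they included Fgf8, listed at 0 in ES cells and at 182 FPKM in control EBs, Gsc, listed at 0 and at 42.1 FPKM, and Eomes, at 2.26 and 41.0 FPKM. Cyp26a1, which encodes an enzyme that degrades retinoic acid, was at 0.962 and 55.5 FPKM. Of 10 notochord and node genes 9 were higher (median 3.07, percentile 100), such as Foxa2 (2.11 and 43.2 FPKM) and Foxj1 (0.661 and 25.4 FPKM). Of 17 genes described downstream of Brachyury 13 were higher and 0 were lower (median 3.36, percentile 100). This list shares members with the streak and node lists. Of 11 primed epiblast genes 9 were higher and 1 was lower (median 1.99, percentile 100), including Fgf5, at 0.177 FPKM in ES cells and 113 in control EBs, and the homeobox gene Otx2, at 6.42 and 107 FPKM. Of 12 epithelial genes 8 were higher and 0 lower (median 1.91, percentile 100), with the keratin gene Krt18 at 23.0 and 316 FPKM.

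Later mesoderm was less uniform. Of 10 paraxial and presomitic mesoderm genes 6 were higher and 1 was lower (median 1.26, percentile 99.7), a median inside the central 95% of random lists with an FPKM floor of 5. Rspo3 was listed at 0 in ES cells and at 13.7 FPKM in control EBs, and Tcf15 was at 133 and 1.34 FPKM. Of 9 lateral plate and cardiac genes 5 were lower and 2 higher (median −1.49, percentile 0.13), led by Tbx3 (69.8 and 0.839 FPKM) and Bmp4 (52.2 and 2.85 FPKM). Tbx3 is also in the naive pluripotency list, and Gata4, another lower member, is also in the extraembryonic endoderm list. Of 6 haemato-endothelial genes 3 were lower and 1, Etv2, was higher (median −1.47, percentile 0.69).

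Of 11 definitive endoderm genes 7 were higher and 2 lower (median 3.40, percentile 100), such as Cer1, which encodes a secreted Nodal antagonist and was listed at 0 in ES cells and at 56.7 FPKM in control EBs, and Cxcr4, at 0.270 and 31.1 FPKM. Of 16 extraembryonic endoderm genes 12 were lower and 1 was higher (median −2.13, percentile 0), with the laminin genes Lama1 at 92.9 and 4.88 FPKM and Lamc1 at 137 and 12.6 FPKM. Sox17 belongs to both endoderm lists and its direction was left open. The table for ES cells and control EBs gave it 26.3 and 0.312 FPKM, whereas the other table gave the same control library 26.3 FPKM. Leaving out Sox17 with all other genes whose control values differed over 1.5-fold between the tables gave list medians of 3.61 and −2.13.

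Among signalling lists, Notch genes (6 of 10 higher, 0 lower; median 1.10, percentile 99.8), BMP genes (6 of 13 higher, 1 lower; median 0.96, percentile 99.4) and Wnt target genes (5 of 11 higher, 2 lower; median 0.98, percentile 99.6) had medians above the central 95% of random lists, but inside it with an FPKM floor of 5. The DNA methylation and imprinting list was mixed, with 7 of 14 genes lower and 3 higher (median −1.04, percentile 0.15). Tet1 was at 46.0 FPKM in ES cells and 2.68 in control EBs, Tet2 at 42.5 and 1.16, and the imprinted gene Peg3 at 4.80 and 50.6. Of 12 unfolded protein and amino acid stress genes 6 were lower and 0 higher (median −1.01, percentile 0.10), including Chac1 (22.2 and 2.06 FPKM) and Trib3 (27.9 and 5.16 FPKM). Of 12 housekeeping genes 8 stayed within 2-fold (median 0.45, percentile 74.8), and B2m was at 11.2 and 115 FPKM.

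In all, 2228 of 13972 genes were higher in control EBs and 2726 were lower, and 355 and 220 of these were listed at 0 in the lower library. The authors' deposited table gave an unadjusted p under 0.05 to 1672 and 1937 of them, a comparison of 2 libraries and not of conditions. That p was under 0.05 for every gene listed at 0 in 1 library alone, whatever its level. Outside the fixed lists, the highest genes included Cxx1c (0.328 and 96.7 FPKM; X chromosome, with near-identical paralogs, so uncertain) and Cfc1 (listed at 0 and at 45.2 FPKM), and the lowest were Laptm5 (120 and 0.207 FPKM) and Sept1 (241 and 2.32 FPKM). The median log2 ratio of genes at 1 FPKM or more in both libraries was −0.11, so differences are relative to values lower by that much in control EBs.

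**Figure D1:**
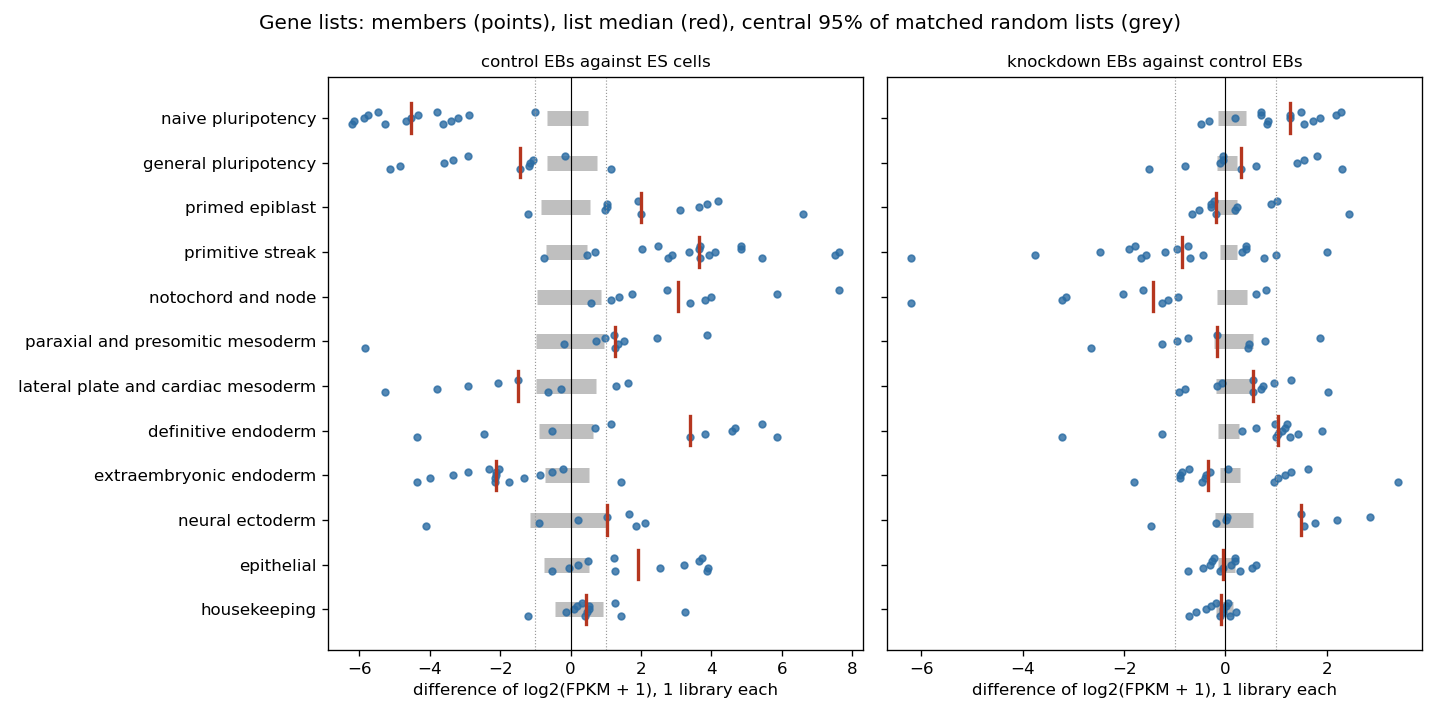
Difference of log2(FPKM + 1) for the measured members of 12 gene lists (points), with the list median (red line) and the central 95% of matched random lists (grey bar), for control EBs against ES cells (left) and knockdown EBs against control EBs (right), 1 library per group. Naive pluripotency had a median of −4.54 on the left and 1.28 on the right, and primitive streak 3.66 and −0.85; Sox17, whose direction on the left was left open, is among the points of both endoderm lists.

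The second comparison asked which genes differed in day 4 EBs when Brachyury was knocked down. The medians of the node and streak lists were lower in the knockdown library, whereas those of the definitive endoderm and naive pluripotency lists were higher. Of 16 measured genes described downstream of Brachyury 10 were lower and 0 higher (median log2 difference −1.22, percentile 0). Foxj1, a regulator of motile cilia, was at 25.4 FPKM in control EBs and 1.96 in knockdown EBs. The Wnt agonist gene Rspo3 was at 13.7 and 1.32 FPKM, the transcription factor gene Sp5 at 14.4 and 1.77, and Fgf8 at 183 and 48.1. Of 10 notochord and node genes 7 were lower and 0 higher (median −1.43, percentile 0), with the BMP antagonist gene Chrd at 13.1 and 2.47 FPKM and the keratin gene Krt19 at 65.9 and 6.10 FPKM. Of 18 primitive streak genes 8 were lower, 1 was higher and 9 were within 2-fold (median −0.85, percentile 0). Both lists hold T itself, and without it 6 of 9 node genes (median −1.25, percentile 0) and 7 of 17 streak genes (median −0.74, percentile 0) were lower, a setting added after seeing the data. Wnt8a was at 20.8 and 0.604 FPKM. The higher one was Amot, at 64.6 and 261 FPKM. Eomes (41.0 and 29.7 FPKM), Gsc (42.1 and 52.9 FPKM) and Lhx1 (27.5 and 36.5 FPKM), chosen after their values were seen, were within 2-fold.

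Of 13 definitive endoderm genes 8 were higher and 2 lower in the knockdown library (median 1.04, percentile 100). Sox17 was at 26.3 FPKM in control and 55.1 in knockdown EBs, Hhex at 8.16 and 23.9, and Foxa1 at 2.39 and 7.22. The lower members were Krt19 and Foxa2 (42.8 and 17.4 FPKM), both also in the node list. In the extraembryonic endoderm list the count and the median pointed in opposite directions, with 5 of 16 genes higher, 1 lower and a median of −0.34 (percentile 0), which became 0.049 with an FPKM floor of 5. Hnf4a, a regulator of hepatic and visceral endoderm genes, was at 0.250 and 12.2 FPKM, in a locus of 4 genes, and the laminin gene Lama1 at 4.88 and 0.690 FPKM.

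Of 15 naive pluripotency genes 8 were higher in the knockdown library and 0 were lower (median 1.28, percentile 100). Dppa5a was at 97.6 FPKM in control EBs and 359.9 in knockdown EBs, against 1039 in ES cells. Zfp42 was at 5.51 and 28.5 FPKM, and Esrrb at 1.33 and 6.69. Of 11 general pluripotency genes 4 were higher and 1 was lower (median 0.30, percentile 99.4), with a median of 0.13 and inside the central 95% at an FPKM floor of 5. The lower one was Tdgf1, which encodes the Nodal co-receptor Cripto, at 138 and 48.0 FPKM. Of 11 primed epiblast genes 9 were within 2-fold and 2 were higher (median −0.18, percentile 1.88), Fgf15 (4.33 and 28.0 FPKM) and Otx2 (107 and 218 FPKM).

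Of 9 neural ectoderm genes 5 were higher and 1 was lower in the knockdown library (median 1.49, percentile 100). Hesx1, a homeobox gene of the anterior neural plate, was at 3.31 and 18.7 FPKM, against 0.369 in ES cells. Tubb3 was at 0.487 and 9.75 FPKM, against 24.7 in ES cells. The list median was inside the central 95% of random lists without an FPKM floor (0.23) and with genes listed at 0 in either library left out (0.031). Among mesoderm lists, 2 of 11 lateral plate and cardiac genes were higher and 0 lower (median 0.55, percentile 97.8, inside the central 95% with pseudocounts of 0.1 and 0.5 or a floor of 5), and 2 of 9 paraxial genes were lower and 1, Tcf15, was higher (median −0.16, percentile 4.56, outside the central 95% without a floor at −0.24). Etv2 was the 1 haemato-endothelial gene of 6 to differ, at 5.37 and 1.21 FPKM.

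Signalling genes split within lists. Of 12 BMP genes 2 were higher, Id1 (64.8 and 138 FPKM) and Id2 (11.7 and 42.9 FPKM), and 1 was lower, Bmp7 (11.6 and 2.90 FPKM), with a median of 0.56 (percentile 99.7). Of 11 Wnt target genes 2, Sp5 and Axin2 (7.64 and 1.51 FPKM), were lower and 1 was higher (median −0.28, percentile 0.28). Of 11 Nodal and TGF-beta genes 3 were higher and 1 was lower (median 0.77, percentile 100), and of 14 FGF and ERK genes 2 were higher and 1 was lower (median −0.18, percentile 0.82), which became 0.025 with an FPKM floor of 5. Of 9 interferon genes 3 were lower and 1 was higher (median −0.60, percentile 0.03), a median of −0.072 inside the central 95% without an FPKM floor, with Cxcl10, in a locus of 4 genes, at 6.65 FPKM in control EBs and 0.253 in knockdown EBs. All 21 cell cycle genes (median −0.19, percentile 0.08), all 13 epithelial genes (median −0.052, percentile 21.5) and all 12 housekeeping genes (median −0.084, percentile 19.9) were within 2-fold.

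**Figure D2:**
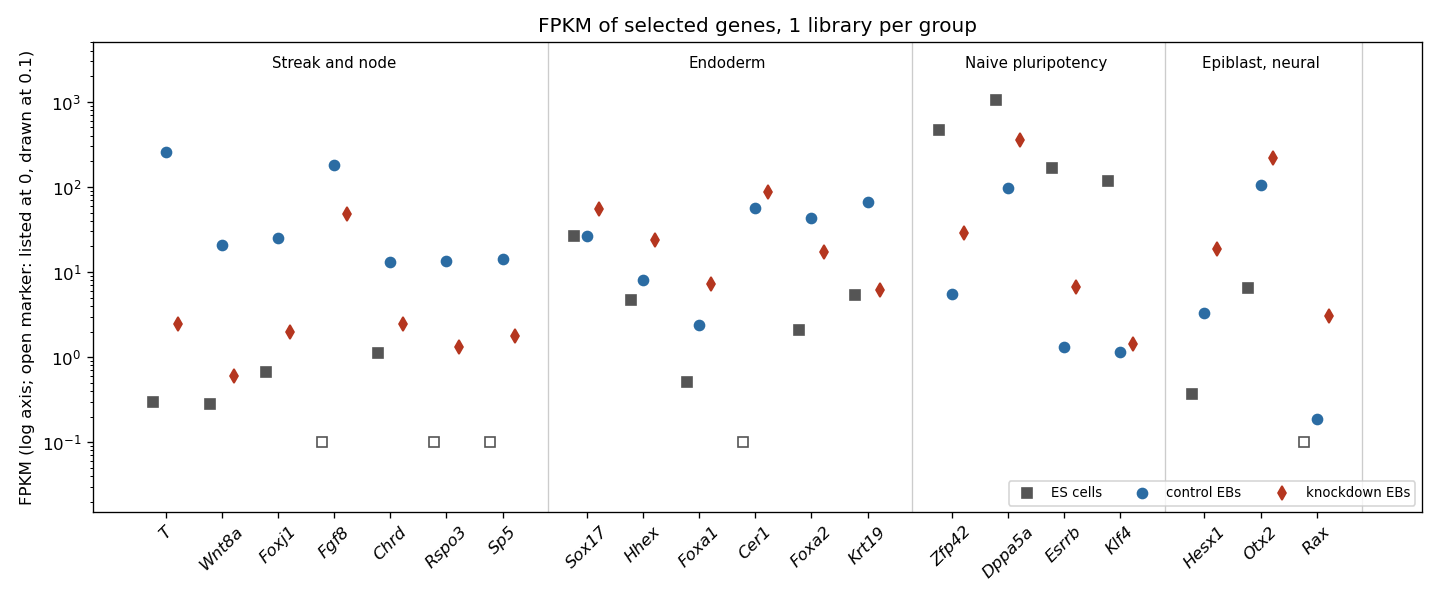
FPKM (log axis) of 20 genes in ES cells (squares), control EBs (circles, second quantification) and knockdown EBs (diamonds), 1 library each, with values listed at 0 drawn as open squares at 0.1. T was at 0.297, 254 and 2.47 FPKM and Zfp42 at 467, 5.51 and 28.5 FPKM; the ES cell value of Sox17 is the one whose assignment was left open.

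In all, 742 of 13821 genes were higher in the knockdown library and 353 were lower, and 83 and 38 of these were listed at 0 in the lower library. The counts were 406 and 231 with an FPKM floor of 5 and 1181 and 544 with a pseudocount of 0.1. The authors' deposited table gave an unadjusted p under 0.05 to 389 and 202 of them. That p was under 0.05 for every gene listed at 0 in 1 library alone, whatever its level. Among the highest were the secreted Wnt antagonist gene Sfrp5 (0.860 and 30.0 FPKM) and Spink3 (11.0 and 169 FPKM), both outside the fixed lists, and Grb10 (6.86 and 105 FPKM), from the imprinting list. The lowest after T were Cxx1c (96.8 and 2.12 FPKM), Igfbp3 (145 and 7.38 FPKM), the lipoxygenase gene Alox15 (26.8 and 0.609 FPKM) and Ltb (25.6 and 0.546 FPKM), followed by Wnt8a, Fgfbp1 (85.2 and 6.09 FPKM) and Tagln (65.7 and 4.84 FPKM, in a locus of 6 genes). Cxx1a (31.5 and 5.39 FPKM) and Cxx1b (37.8 and 5.78 FPKM), paralogs of Cxx1c, were also lower, and how reads were divided among them is not known here. Pseudogenes made up 25.9% of the higher genes, 14.7% of the lower genes and 11.6% of the genes compared. In control EBs against ES cells they made up 18.5% of the higher genes, 8.80% of the lower genes and 11.1% of the genes compared. The highest genes in the knockdown comparison included H3f3c (4.07 and 223 FPKM) and H3f3a-ps2 (16.6 and 301 FPKM), near-identical copies of H3f3a (401 and 214 FPKM), so these are uncertain.

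The third comparison asked whether genes that differed between ES cells and control EBs also differed in the knockdown. Over 13088 genes measured in both tables, 223 of the 349 genes lower in knockdown EBs were higher in control EBs than in ES cells, including T, Fgf8, Foxj1, Rspo3 and Sp5. Independent lists of these sizes would share 58.9. Of the 501 genes higher in knockdown EBs 214 were lower in control EBs than in ES cells, including Zfp42, Esrrb and Dppa4, against 82.8 for independent lists. Genes had to reach 1 FPKM in at least 1 library of each table. This kept 349 of the 353 genes lower in the knockdown but 501 of the 742 higher. A gene under 1 FPKM in control EBs entered only if ES cells reached 1 FPKM, which favours genes lower in control EBs. The 82.8 can therefore be too low. The same direction in both comparisons was seen for 107 higher genes (84.5 for independent lists) and 33 lower genes (57.7).

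Both comparisons used the same control library, whose errors push them in opposite directions. Simulated unchanged libraries with the error implied by the authors' p gave overlaps of 770 and 295 genes in the opposite directions. They also gave 2207 knockdown differences against the 850 observed, and a covariance of the log2 differences of −0.46 against −0.17, so this error was too large to serve as a measure of no change. At an FPKM floor of 20 it gave 113 knockdown differences against 159 observed, overlaps of 68.1 and 3.76 against 61 and 31, and a covariance of −0.36 against −0.16. A simulation with 0.7 of that error was fitted to the observed number of knockdown differences, so it counts all of them as error and its overlaps are not used. For the same direction the authors' error gave 29.9 higher and 29.6 lower genes against the 107 and 33 observed, and 0.310 and 0.280 against 26 and 4 at a floor of 20, and the same limit applies to these. Part of either overlap can come from sharing the control, and how much was not settled, since the control was 1 library.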

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

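The settings that leave out genes listed at 0, genes with differing control values or genes that are not protein-coding were chosen after seeing the data; the others were planned. Counts of genes, overlaps and T stayed within 1.5-fold in 52 of 74 recomputed values, and no direction of T changed. A 3-fold rule gave 996 higher and 1194 lower genes in control EBs than in ES cells, 302 higher and 124 lower genes in knockdown EBs, and overlaps of 79 and 68, by construction. A floor of 5 FPKM left 406 higher and 231 lower knockdown genes and an overlap of 107 for genes lower in control EBs and higher in the knockdown. A pseudocount of 0.1 gave 1181 and 544 knockdown genes, an overlap of 407 for that same pair and 9.32 for T between control EBs and ES cells, and a pseudocount of 0.5 gave 8.32 for T. Protein-coding genes alone gave 457 higher knockdown genes. Adding the authors' p left 389 and 202 knockdown genes. Among genes with p under 0.05 in the authors' deposited tables, 8009 and 3521, those at 1 FPKM or more were 5311 and 1592, and those above 0 in both libraries 5059 and 1879. Leaving out genes listed at 0 gave an overlap of 147 for genes higher in control EBs and lower in the knockdown. Of 506 recomputed list medians 476 kept their side of the central 95% of random lists, 22 lost it, 4 gained it and 4 changed sign. A change of sign was counted whether or not the new median lay outside the central 95%. Those gained were all in the knockdown: surface ectoderm (0.69) and paraxial mesoderm (−0.24) without a floor, fibroblast markers (−0.51 with a pseudocount of 0.1) and T-box genes (−0.45 with a floor of 5). Those that changed sign were interferon genes in control EBs against ES cells (−0.69 without genes listed at 0), T-box genes there (−0.10 without a floor), and, in the knockdown with a floor of 5, extraembryonic endoderm (0.049) and FGF and ERK genes (0.025). Of 494 recomputed values of named genes 395 moved by less than 1.5-fold. Where no construction is named, the cause was not tested. Restricting to genes with an OK test status, as planned, was not run, since no such column was used here. No paired analysis was possible because each group has 1 library. Unknown depth limits genes near the floor most.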

Other observations

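Several lists that no comparison above described differed in single members. Among trophoblast genes 3 of 6 were higher in knockdown than in control EBs and 0 were lower (median log2 difference 0.93, percentile 99.4), namely Gata3 (0.469 and 3.98 FPKM), Ascl2 (1.34 and 4.91 FPKM) and Elf5, listed at 0 in control EBs and at 2.93 FPKM in knockdown EBs. This median was inside the central 95% without a floor (0.12) and without genes listed at 0 (0.53). Among germ cell genes 3 of 10 were higher and 1 was lower (median 0.75, percentile 99.9), with Prdm14 at 0.292 and 2.65 FPKM and Dnd1 at 17.3 and 7.67 FPKM, and a median of 0.32 inside the central 95% with a floor of 5 FPKM. Of the higher germ cell genes, Prdm14 and Dppa3 are also in the naive pluripotency list. The imprinted genes Grb10 and Cdkn1c (12.4 and 47.7 FPKM) were higher and Plagl1 (11.2 and 2.85 FPKM) was lower, in a list of 14 with a median of 0.38 (percentile 99.9). Most p53 response, hypoxia and glycolysis, and immediate early genes were within 2-fold. Of these lists 1 of 14 genes (Phlda3), 2 of 17 (Ndrg1 and Ddit4) and 2 of 10 (Atf3 and Junb) were lower and 0 higher, with medians of −0.32 (percentile 0), −0.26 (percentile 0.14) and −0.45 (percentile 0.05). All 12 unfolded protein and amino acid stress genes were within 2-fold (median 0.10, percentile 78.0). Surface ectoderm, Notch, mesenchymal, fibroblast, T-box and haemato-endothelial lists lay within the central 95% of random lists in the knockdown comparison. Outside it were surface ectoderm without a floor (median 0.69), fibroblast markers with a pseudocount of 0.1 (−0.51) and T-box genes with a floor of 5 FPKM (−0.45), where T and 2 other genes were left. Of the fibroblast markers, Dcn was at 0.253 FPKM in control and 9.12 in knockdown EBs, and Tagln and Acta2 (4.84 and 1.01 FPKM) were lower. No two-cell-like gene reached the floor.

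In control EBs against ES cells, neural ectoderm genes (4 of 7 higher, 1 lower; median 1.04, percentile 98.1), interferon genes (5 of 10 higher, 2 lower; percentile 98.1), p53 response genes (4 of 13 higher, 2 lower; median 0.53, percentile 97.9) and T-box genes (3 of 5 higher, 1 lower; median 1.36, percentile 99.3) lay above the central 95%. The neural median was inside it with either other pseudocount, either other floor or the median ratio set to 1. The interferon median was inside it with a floor of 5 FPKM (1.15) or protein-coding genes alone (0.91) and was −0.69 without genes listed at 0, and the T-box median −0.10 without a floor. Of 10 germ cell genes 5 were lower and 4 higher (median −1.04, percentile 0.88), inside the central 95% with a floor of 5 FPKM. Cell cycle genes had 6 of 21 lower (median −0.39, percentile 4.63), including Ccne1 (165 and 34.2 FPKM) and Ccnd3 (174 and 36.1 FPKM). Of 17 hypoxia and glycolysis genes 11 were within 2-fold, 4 were higher and 2 lower (median −0.032, percentile 27.0), with the lactate dehydrogenase gene Ldha at 433 and 1646 FPKM and the hexokinase gene Hk2 at 118 and 12.1 FPKM. Nodal, FGF, mesenchymal, fibroblast, immediate early, surface ectoderm and trophoblast lists lay within the central 95%. The two-cell-like gene Zscan4f was at 1.02 FPKM in ES cells and listed at 0 in control EBs.

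Of the tests that follow, those on known failed estimates, on naive pluripotency genes and on Sox17 were chosen only after the results were seen.

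The 353 genes lower in the knockdown library were weighed against 3 technical explanations. Control values that differ between the tables covered 1.70% of them and setting the median ratio to 1 gave 103.7% of their number, both of which argue against those explanations. Failed FPKM estimates listed at 0 would need these genes at 0 in knockdown EBs, and 315 of them were above 0. The 38 listed at 0 were 10.8%, just over the 10% set in advance as a bound against this explanation. All were above 0 in control EBs, whereas 0% of 187 known failed estimates were at 0 in 1 library alone. Those estimates were found through the control library, so a failure in the knockdown library alone could not be among them. The explanation therefore stays open for the 38 genes. A Brachyury effect stays possible, as does any other difference between these 2 cultures, since each was 1 library.

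Naive pluripotency genes higher in the knockdown library may come from a share of ES-like cells left in the EBs. Of 126 genes with at least 20 FPKM in ES cells and 8-fold lower in the mean of both EB libraries, 68.3% were higher in the knockdown, between the bounds of 60% and 80%. Choosing 144 such genes on the control library alone, which favours low control values, gave 79.2%. The share higher among other genes of similar level was not computed. Over all genes compared 742 were higher and 353 lower in the knockdown, so part of the 68.3% can be a general shift. The share of ES-like cells needed had a median of 2.28% over the 126 genes (quartiles −0.357% and 7.46%) and of 3.20% over 11 naive genes (quartiles 2.06% and 6.96%, from −0.916% to 27.9%). Slower differentiation of the whole culture would lower EB genes. Of 94 genes with at least 20 FPKM in the mean of both EB libraries and 8-fold higher there than in ES cells, 30.9% were lower in the knockdown. Their median log2 difference was 0.24 (quartiles −0.086 and 0.71). With rows at 0 in both libraries of the first table kept, 38.9% of 149 genes were lower. These shares lay under a bound of 60%, which was set after a trial of the test had been seen. Genes that peak before day 4 were not set apart and could be higher in a delayed culture, so the test cannot decide on slower differentiation. A share of ES-like cells, slower differentiation and an effect of Brachyury on these genes cannot be told apart. The 68.3% lay between the bounds for ES-like cells, and each group was 1 library.

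Sox17 was lower in control EBs than ES cells in the first table, against the direction of Cer1, Cxcr4 and Foxa2 and in that of Cpn1, Gata4, Sox7 and most extraembryonic endoderm genes. Its ES cell value there (26.3086 FPKM) was within 0.0133% of the control value in the second table (26.3121 FPKM), while the control value of the first table was 0.312 FPKM. Among 23 genes above 0 with control values over 1.5-fold apart, Sox17 was the 1 gene with such a match within 0.1%, and 0.0145 were expected from the share of matches among all genes. A candidate explanation is that the 2 values of this row were exchanged between ES cells and control EBs, which would make Sox17 higher in control EBs. A chance match with a failed control estimate was not excluded, and no biological explanation was tested.

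Among 16 families of a parent gene and its named pseudogenes with at least 1 copy higher in the knockdown library, the parents had a median log2 difference of −0.10. The 2 H3f3a pseudogenes summed to 17.7 FPKM in control EBs and 372 in knockdown EBs, whereas H3f3b was at 422 and 534 FPKM.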
